A study of Homo sapiens with 16 samples.

How the data were processed

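RNA abundance was measured by sequencing in A549 cells, an established human lung adenocarcinoma line with epithelial features, at 0, 6, 12, 24, 36, 48, 72 and 96 h of an epithelial to mesenchymal transition induced with TGF-beta. Each of the 8 times had 2 libraries, numbered replicate 1 and 2 in the labels, so 16 libraries were used. Total RNA was extracted with Trizol and libraries were built with an Illumina TruSeq RNA kit, per the labels' protocols. The authors deposited gene abundances as TPM, the share of transcripts corrected for gene length, in a table for each replicate number; Bowtie and RSEM are named without versions, per the submitters' processing notes. The genome build and the annotation release are not given in the sources used here. TPM are scaled within each library, so the tables of replicate 1 and replicate 2 could be joined by Ensembl gene identifier. All columns of values were mapped to a library by their time and replicate number.

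The tables held 57773 genes. TPM keep no record of how many reads lie behind a value, so the sequencing depth of each library is unknown, and no counting intervals are given. Genes listed at 0 numbered 29278 to 31187 per library, except 36116 in 36 h replicate 2 and 36294 in 48 h replicate 2. A set of 6 abundant small RNAs (RN7SL1, RN7SL2, RN7SL3, RN7SK, RMRP and RPPH1) took from 42.5% of the TPM in 12 h replicate 1 to 64.1% in 48 h replicate 1. This share changes the scale on which all other genes are expressed. The median log2 fold change of all genes against 0 h was -0.37 at 6 h, 0.03 at 12 h, -0.15 at 24 h, -0.16 at 36 h, -0.46 at 48 h, -0.16 at 72 h and -0.20 at 96 h with TPM as deposited. With TMM scaling these medians lay between -0.05 and 0, so fold changes below are to be read relative to these shifts. No 2 libraries held identical values, and the highest correlation between any pair was 0.989.

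Values were analysed as log2(TPM + 1), and fold changes are on that scale, which understates the change of genes with low TPM. Genes with at least 1 TPM in at least 2 libraries were kept, which left 16967 genes. Differences were tested with limma 3.58.1 in R 4.3.3 (linear model with 1 mean per time, empirical Bayes moderation with a mean trend, two-sided). All 8 times shared the estimate of the spread, because 2 libraries per time give too little on their own. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p below 0.05. An exact permutation test of 2 against 2 libraries cannot give a p below 0.333, so none was used. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Every time was compared with 0 h, each time with the one before it, and 96 h with 6 h; a moderated F test covered the whole course. Genes were also sorted into 6 trajectory classes from their calls at 6 and 96 h with a log2 fold change of at least 1 in size.

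A collection of 43 gene lists was written before the data were examined, with markers of other cell types and of RNA quality among them; 39 had at least 5 members past the filter. They were tested at 6, 24 and 96 h with camera (preset correlation of 0.01), adjusted over lists and the 3 times. No list call of camera against 0 h, on the TPM as deposited and without a block, held with an estimated correlation. With TMM scaling, the replicate block and an estimated correlation together, 0 lists were called at 6 h and 4 each at 24 and 96 h. The fry test, which asks whether the members of a list move one way on balance without comparing them with other genes, was run as an alternative. Of the lists for other cell types, the fibroblast list had 2 of 12 members past the filter (highest MFAP4, mean 1.04 TPM), the endothelial list 1 of 9 matched (ESAM, 3.19 TPM), the leukocyte list 4 of 12 (CD68, 5.55 TPM), the erythroid list 0 of 7 (HBA1, 0.0762 TPM) and the nerve and muscle list 6 of 10 (TUBB3, 96.5 TPM).

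Libraries with the same replicate number deviated together from the means of their times: the correlation of these deviations was above 0.1 in 28 of 28 pairs of times, with a lowest value of 0.128 and a median of 0.438. With TMM scaling it was above 0.1 in 27 of 28, with a lowest value of 0.0821. The numbers in the labels were therefore treated as a possible pairing of the samples. The main fits held no replicate block, because the labels do not say that a replicate number is a shared batch. Their calls and p-values leave the pairing out, and values with a replicate block stand beside many results that the block changes.

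The genes named were set by a rule before the data were examined. It took the 10 largest rises and falls at 6, 24 and 96 h among called genes with a mean of at least 5 TPM in the higher group and no overlap between the libraries compared, the 3 largest for each step between times, up to 2 rising and 2 falling called members of each list, and the 5 largest of each trajectory class. A fixed set of 24 markers of the transition was added whatever their result. Genes from the end of each ranking were left out for length. Some other genes that the rule names are not reported here. SDPR, RP11-215G15.5, EGR1 and FOS were named after their values were seen. Members of families with near-identical sequence (AKR1C1, AKR1C2 and AKR1C3; AKR1B10; CYP4F3; IGFL1, IGFL2 and IGFL3; CGB8) are uncertain, because reads can be split between copies. Gene positions are from GENCODE release 29 on GRCh38, matched by Ensembl identifier for 52338 of the 57773 genes.

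Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter, a filter of 5 TPM, TMM-type scaling factors (a trimmed mean of log ratios, computed on the TPM), quantile normalization, the replicate block, no mean trend, robust moderation, a fit of only the times compared, and leaving out each library in turn. Chosen after seeing the data were TMM scaling together with the block, TPM rescaled without the 6 small RNAs, TPM rescaled over protein-coding genes, leaving out both 6 h replicate 1 and 48 h replicate 1, and, for lists, TMM scaling with the block and an estimated correlation. The procedure was tested on simulated data for 24 h against 0 h, with 200 of 16967 genes changed in each of 5 draws. These were taken from the more abundant genes, and the other NRF2 targets were lowered by 1 on the log2 scale as well. It found 16.5% of changes of 1 on the log2 scale, 87.0% of changes of 2 and 96.4% of changes of 3, and 3.96% of its calls were false. The simulated noise was independent between genes and between libraries, without the shared deviations of a replicate number. These rates may therefore be better than those in the data. Plots were made with matplotlib 3.10.9.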

Results

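RNA-seq of A549 cells covered 8 times of a TGF-beta-induced epithelial to mesenchymal transition, the loss of epithelial and gain of mesenchymal features, with 2 libraries at each of 0, 6, 12, 24, 36, 48, 72 and 96 h. Values are TPM, and errors are SD over the 2 libraries (n = 2) unless given as the SE of a log2 fold change from limma. The depth of the libraries is unknown, because TPM keep no read totals. There were no untreated cultures at the later times, so the effect of TGF-beta cannot be separated from that of time in culture. Every comparison with 0 h rests on the same 2 libraries: most calls of named genes were lost without 0 h replicate 2, and many without 0 h replicate 1.

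**Figure D1:**
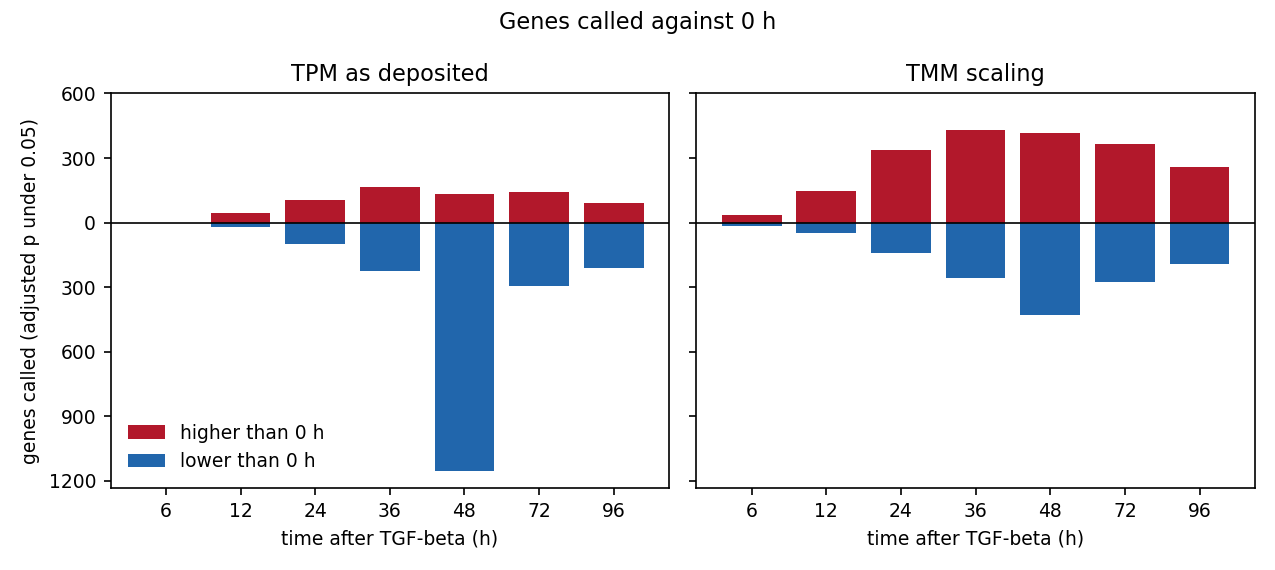
Genes called higher (red, upward) or lower (blue, downward) than at 0 h by limma at each time (x axis, hours; y axis, number of genes), with TPM as deposited on the left and with TMM scaling on the right. At 48 h, 135 genes were higher and 1154 lower as deposited, against 415 higher and 428 lower with TMM scaling.

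The comparison of 6 h with 0 h asked which genes respond early. GDF15, a stress-induced secreted member of the TGF-beta family on chromosome 19 (18374731 to 18389176 on GRCh38), fell from 42.2 ± 5.10 TPM at 0 h to 3.60 ± 1.65 TPM at 6 h. Its log2 fold change was -3.27 (SE 0.40, adjusted p = 0.0222 by limma). The other called genes, named after their values were seen, were SDPR, a caveola component, which fell from 10.1 ± 2.33 to 1.51 ± 0.516 TPM, and the non-coding transcript RP11-215G15.5, which fell from 5.08 ± 0.884 to 0.485 ± 0.304 TPM.

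None of the SMAD-induced targets measured was called at 6 h, with or without the replicate block. Of these 21 targets, 8 were called higher with TMM scaling and the block together, chosen after the data were seen. COL4A1, a basement membrane collagen, measured 23.8 ± 13.5 TPM at 0 h and 63.6 ± 5.87 TPM at 6 h, with a log2 fold change of 1.49 (SE 0.64, adjusted p = 0.357 by limma). The feedback regulators SKIL and SMAD7 measured 54.2 ± 10.8 and 109 ± 9.57 TPM, and 12.3 ± 5.73 and 20.6 ± 0.919 TPM. CDH1, which encodes E-cadherin, measured 21 ± 9.23 and 8.91 ± 5.02 TPM, with no call. ID1, a target of BMP signalling, measured 75.3 ± 12.0 and 145 ± 10.5 TPM. As a group, the 21 measured SMAD-induced targets were higher relative to other genes (median log2 fold change 0.45, camera adjusted p = 3.5e-17), although 0 of them were called singly and 2 were called higher when adjusted over the list alone. The adjusted p of this list was 0.60 with an estimated correlation and 0.59 by fry. Members lay on both sides of 0 as deposited, and 21 of 21 above it with TMM scaling. The 13 mitochondrially encoded transcripts, a sign of RNA quality, had a median of -1.32 at 6 h, -1.42 and -1.22 in replicates 1 and 2 (camera adjusted p = 0.111, 0.000735 with the replicate block and 0.0379 with TMM scaling; adjusted p = 0.897 with an estimated correlation).

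In all, 0 genes were called higher and 3 lower at 6 h by limma. With the replicate block the counts were 4 and 8, with TMM scaling 35 and 14, and without any single library of either time 0. With TMM scaling and the block together they were 264 and 95.

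Genes called higher at 24 h included collagens and other matrix genes, and those called lower included NRF2 targets of oxidant defence and genes of epithelial adhesion and secretion. The largest rise was in IGFL1, an insulin growth factor-like gene on chromosome 19 (46229752 to 46231243), which went from 0.945 ± 0.134 to 205 ± 147 TPM, with a log2 fold change of 6.51 (SE 0.86, adjusted p = 0.00532 by limma). CGB8, a chorionic gonadotropin beta gene with near-identical copies whose reads could be shared, rose from 0.635 ± 0.276 to 30.8 ± 2.99 TPM. TAGLN, an actin-binding protein of smooth muscle, rose from 21.6 ± 24.1 to 287 ± 46.6 TPM. TNFAIP6, a hyaluronan-binding matrix protein, rose from 0.430 ± 0.240 to 26.3 ± 4.19 TPM, and SLN, a regulator of the calcium pump, from 0.115 ± 0.0636 to 19.4 ± 5.19 TPM.

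Further rises at 24 h were in ADAM19, a membrane metalloprotease (log2 fold change 4.10), NPTX1, a secreted pentraxin (4.07), COL22A1, a collagen of tissue junctions (4.05), and IL11, a cytokine of the IL-6 family (3.74).

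AGR2, a protein disulfide isomerase of secretory epithelium on chromosome 7 (16791811 to 16833433), had the largest fall at 24 h, from 116 ± 70.9 to 3.96 ± 2.80 TPM (log2 fold change -4.54, SE 0.70, adjusted p = 0.0101 by limma). CDH1, the E-cadherin gene of epithelial junctions, lies on chromosome 16 (68737225 to 68835548) and fell from 21.0 ± 9.23 to 1.90 ± 1.16 TPM, with a log2 fold change of -2.92 (SE 0.62, adjusted p = 0.0427 by limma). GDF15 was at 2.63 ± 0.148 TPM. The chemokine CXCL5 fell from 49.4 ± 6.39 to 5.49 ± 2.0 TPM, and the EGF receptor ligand AREG from 22.8 ± 0.735 to 2.19 ± 0.297 TPM. INHBB, an activin subunit, fell with a log2 fold change of -2.93, CA12, a carbonic anhydrase, with -2.92, OSGIN1, an oxidant-induced gene, with -2.88, CYP4F3, a fatty acid hydroxylase, with -2.80, and AKR1B10, an aldo-keto reductase, with -2.60.

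Of the 21 SMAD-induced targets, 2 rose at 24 h (9 when adjusted over the list alone, 8 with the replicate block), among them TGFBI, a matrix protein, from 512 ± 282 to 2939.7 ± 18.5 TPM. The list was higher relative to other genes (median 1.23, camera adjusted p = 7.2e-16, adjusted p = 0.60 with an estimated correlation). Of the 21 measured collagens, 4 rose (7 adjusted over the list alone, 8 with the block), COL4A1 among them, from 23.8 ± 13.5 to 306 ± 20.7 TPM (camera adjusted p = 1.2e-08, adjusted p = 0.63 with an estimated correlation). The 24 contractile and focal adhesion genes held 2 that rose (3 adjusted over the list alone, 7 with the block), TAGLN and the smooth muscle calponin CNN1 (0.460 ± 0.198 to 7.78 ± 4.19 TPM), with a camera adjusted p = 4e-12 and an adjusted p = 0.63 with an estimated correlation.

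Other matrix and adhesion genes that rose at 24 h were THBS1, a matricellular activator of latent TGF-beta (43.5 ± 21.7 to 418 ± 154 TPM), P4HA3, a collagen prolyl hydroxylase (9.64 ± 6.75 to 68.1 ± 2.50 TPM), ITGB6, an epithelial integrin subunit that activates latent TGF-beta (5.11 ± 2.43 to 26.3 ± 2.57 TPM), and NT5E, an ectonucleotidase used as a mesenchymal marker (15.0 ± 0.156 to 65.4 ± 7.05 TPM). IGFBP7, BMP6, IER3 and the small heat shock protein gene HSPB1 also rose, with log2 fold changes of 2.42, 2.08, 1.84 and 2.11. Among 15 measured mesenchymal adhesion genes and markers, 2 rose (7 adjusted over the list alone, 8 with the block), with a camera adjusted p = 4.2e-08 and an adjusted p = 0.60 with an estimated correlation. With TMM scaling, the replicate block and an estimated correlation together, chosen after the data were seen, 4 lists were called at 24 h: this list (adjusted p = 0.0327), the contractile genes (0.0488), collagen-modifying enzymes (0.0299) and extracellular proteases and inhibitors (0.0488).

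Of the 27 measured targets of NRF2, the transcription factor of the oxidant response, 7 fell at 24 h and 0 rose. Adjusted over the list alone 23 fell, and with the replicate block 21 fell. This list had the smallest camera p of the 39 lists at 24 h (median -1.25, camera adjusted p = 4.6e-22, fry adjusted p = 0.0027, and adjusted p = 0.12 with an estimated correlation). Of 11 measured mucin and secretory genes, 2 fell (7 adjusted over the list alone, 5 with the block): AGR2 and SPDEF, a transcription factor of goblet cells (4.6 ± 2.43 to 0.150 ± 0.0849 TPM). Their list had a camera adjusted p = 1.5e-06, a fry adjusted p = 0.016 and an adjusted p = 0.41 with an estimated correlation. Of 29 epithelial junction and identity genes, 3 fell, among them CDH1 and the polarity gene LLGL2 (28.2 ± 1.74 to 7.07 ± 0.361 TPM), and 1 rose, the tight junction claudin CLDN4 (1.58 ± 0.191 to 20.3 ± 7.67 TPM). Adjusted over the list alone, 9 fell and 2 rose, and with the block 6 fell and 1 rose (camera adjusted p = 0.01, fry adjusted p = 0.196, adjusted p = 0.74 with an estimated correlation). The EGF receptor ligand EREG and the chemokine CXCL1 fell with log2 fold changes of -2.50 and -2.44.

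Of the fixed markers of the transition not called at 24 h, VIM, the mesenchymal intermediate filament gene, measured 524 ± 41.1 and 996 ± 22.8 TPM at 0 and 24 h, CDH2 (N-cadherin) 26.6 ± 14.3 and 70.9 ± 26.3 TPM, FN1 (fibronectin) 109 ± 36.6 and 358 ± 99.7 TPM, MMP2 2.33 ± 2.71 and 38.3 ± 28.9 TPM, and COL1A1 2.74 ± 2.01 and 61.4 ± 46.3 TPM. With the replicate block these were called, with adjusted p of 0.0274, 0.00585, 0.00328, 0.000395 and 0.00186 by limma. CTGF measured 17.5 ± 15.0 and 155 ± 105 TPM and SNAI1, a repressor of E-cadherin, 0.600 ± 0.410 and 4.70 ± 1.71 TPM; both were called with the block (adjusted p = 0.0142 and 0.00583 by limma). ZEB1 measured 13.4 ± 0.424 and 21.4 ± 3.92 TPM, ID3 63.0 ± 9.62 and 103 ± 2.46 TPM, and KRT18 2389 ± 487 and 1524 ± 401 TPM, with no call under the block either.

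Among markers of other cell types, 1 rose at 24 h, the endothelial adhesion gene ESAM, from 0.46 ± 0.127 to 5.41 ± 1.26 TPM (adjusted p = 0.018), and 1 fell, the leukocyte gene CD14, from 1.44 ± 0.544 to 0.1 ± 0.0283 TPM (adjusted p = 0.0433).

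In all, 104 genes were called higher and 101 lower at 24 h by limma, against 317 and 326 with the replicate block and 337 and 141 with TMM scaling. The count was 1 without 24 h replicate 2 or 0 h replicate 2, 25 without 24 h replicate 1 and 53 without 0 h replicate 1; CDH1, LLGL2 and AKR1B10 missed the threshold with TMM scaling (adjusted p = 0.0572, 0.0769 and 0.0661).

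**Figure D2:**
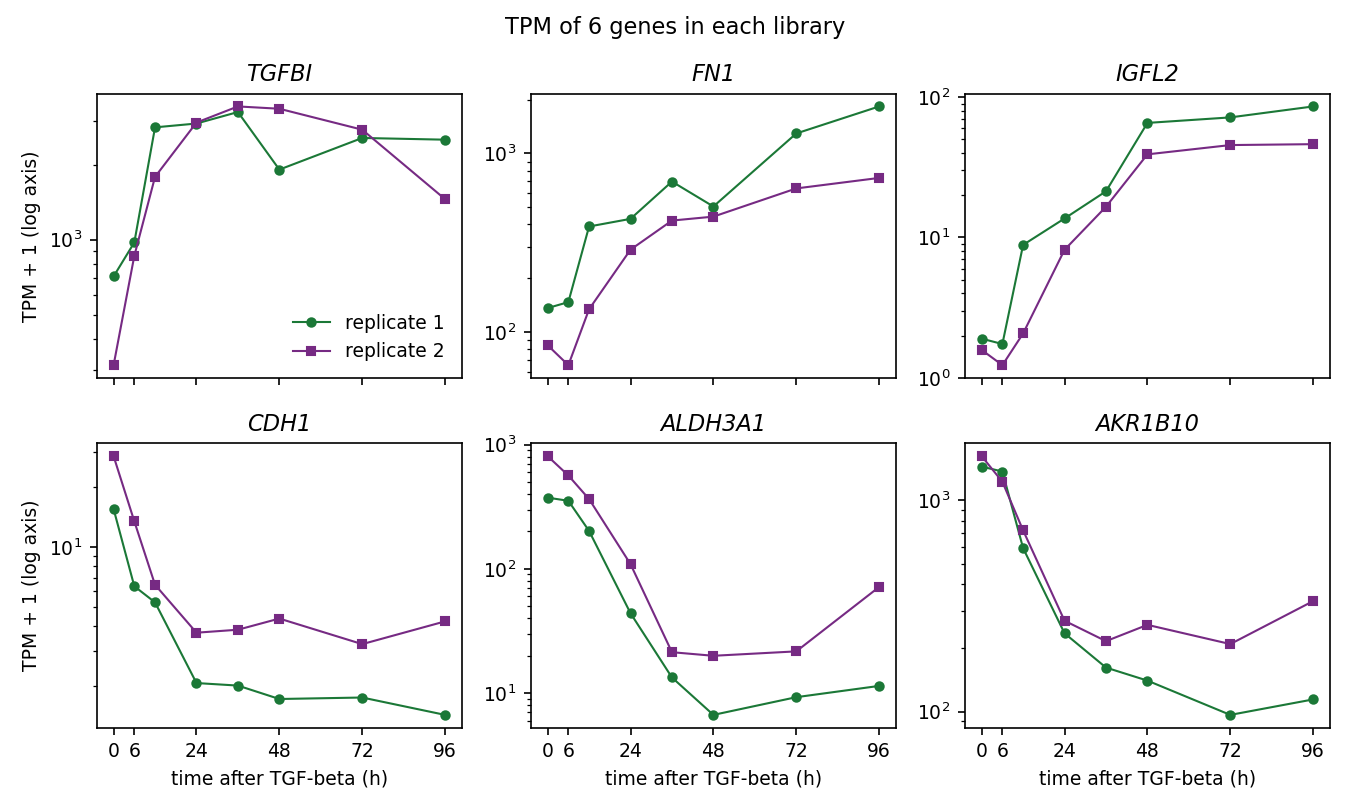
TPM + 1 on a log axis (y) against time (x, hours) for 6 genes, 1 line for each replicate number and 1 point for each library. TGFBI was above the 0 h library of the same replicate number in every later library, FN1 and IGFL2 were highest at 96 h in both replicates, and CDH1, ALDH3A1 and AKR1B10 were below the 0 h library of the same replicate number in every later library.

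At 96 h, the largest rises were in insulin growth factor-like genes and in matrix and protease genes. IGFL2 rose from 0.740 ± 0.226 to 65.0 ± 28.0 TPM (log2 fold change 5.18, SE 0.57, adjusted p = 0.00168 by limma), and IGFL1 and IGFL3, its neighbours on chromosome 19, rose with log2 fold changes of 5.03 and 4.43. MMP2, a gelatinase that cleaves basement membrane collagen, rose from 2.33 ± 2.71 to 111 ± 97.2 TPM, and COL22A1 from 0.190 ± 0.127 to 45.5 ± 42.7 TPM. ITGA11, a collagen-binding integrin subunit, SERPINE2, a protease inhibitor, NPTX1 and ADAM19 rose with log2 fold changes of 4.08, 3.96, 3.67 and 3.56.

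FN1, on chromosome 2 (215360440 to 215436172), rose to 1279 ± 780 TPM at 96 h (log2 fold change 3.43, SE 0.58, adjusted p = 0.0108 by limma). Also higher were GREM1, a secreted BMP antagonist (2.38 ± 0.198 to 30.9 ± 14.2 TPM), VCAN, a matrix proteoglycan (58.0 ± 13 to 304 ± 136 TPM), THBS1 (log2 fold change 3.08), TGFBI (2.02) and SOX4, a transcription factor induced by TGF-beta (1.70).

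The largest falls at 96 h were in AGR2 (116 ± 70.9 to 3.10 ± 3.34 TPM, log2 fold change -4.98), the aldehyde dehydrogenase ALDH3A1 (590 ± 306 to 40.4 ± 42.4 TPM) and the epithelial surface glycoprotein CEACAM6 (25.5 ± 17.4 to 0.380 ± 0.170 TPM). INHBB and SLPI, an epithelial protease inhibitor, fell with log2 fold changes of -3.48 and -3.47. The drug efflux transporter ABCG2, CYP4F3, CA12, the aldo-keto reductase AKR1C2 and OSGIN1 followed with -3.39, -3.33, -3.32, -3.28 and -3.16. CDH1 was at 1.84 ± 1.98 TPM (log2 fold change -3.09, SE 0.62, adjusted p = 0.0240 by limma).

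Of the 27 NRF2 targets, 19 fell at 96 h and 0 rose. Adjusted over the list alone 26 fell, and with the replicate block 25 fell. The members called included AKR1B10 (1526 ± 123 to 223 ± 155 TPM), AKR1C2 (1569.6 ± 84.4 to 212 ± 195 TPM) and ALDH3A1. The median log2 fold change was -1.86 (camera adjusted p = 4e-29, fry adjusted p = 0.0008, and adjusted p = 0.10 with an estimated correlation). Of 11 mucin and secretory genes 5 fell (8 adjusted over the list alone, 8 with the replicate block), with AGR2 and SPDEF among them. Of 29 epithelial junction and identity genes 7 fell (14 adjusted over the list alone, 11 with the block). KRT18 and KRT19, the keratins of simple epithelia, fell from 2389 ± 487 to 978 ± 7.56 TPM and from 50.1 ± 0.304 to 10.8 ± 11.2 TPM, and LLGL2 fell with a log2 fold change of -1.99. These 2 lists had camera adjusted p of 7.3e-09 and 1.4e-05, and fry adjusted p of 0.0039 and 0.016. With an estimated correlation their camera adjusted p were 0.22 and 0.60.

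Genes of DNA replication and sterol synthesis were lower relative to other genes at 96 h by camera. Of 30 S-phase genes, 1 fell, CDC6, a licensing factor of replication (35.5 ± 1.0 to 8.72 ± 0.127 TPM). Adjusted over the list alone 23 fell, and with the replicate block 3 fell (median -1.11, camera adjusted p = 2e-12, adjusted p = 0.74 with an estimated correlation). Of 24 sterol synthesis and uptake genes, 1 fell, HMGCS1, an early enzyme of the pathway (103 ± 15.4 to 17.5 ± 4.55 TPM). Adjusted over the list alone 16 fell, and with the block 4 fell (median -1.13, camera adjusted p = 2.8e-08, adjusted p = 0.74 with an estimated correlation). MKI67, a proliferation marker, measured 55.1 ± 6.11 and 26.2 ± 25.2 TPM, and CDKN1A, an inhibitor of cell cycle kinases, 39.6 ± 16.1 and 47.5 ± 32.0 TPM, with no call for either. The median of the sterol genes was -1.57 and -0.80 in replicates 1 and 2, and -1.65 and -0.19 with TMM scaling; that of the S-phase genes was -0.99 and -1.28, and -1.02 and -0.71 with TMM scaling. The fry adjusted p was 0.27 for the sterol genes and 0.249 for the S-phase genes.

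Among mesenchymal adhesion genes and markers, 3 of 15 rose at 96 h (8 rose and 1 fell adjusted over the list alone; 7 rose and 1 fell with the replicate block; camera adjusted p = 1.1e-10, adjusted p = 0.55 with an estimated correlation). Among transcription factors of the transition, 1 of 14 rose, SOX4 (2 adjusted over the list alone, 4 with the block; camera adjusted p = 1.4e-06, adjusted p = 0.63 with an estimated correlation). With TMM scaling, the block and an estimated correlation together, the 4 lists called at 96 h were both of these (adjusted p = 0.0299 and 0.0488), collagen-modifying enzymes (0.0488) and integrins (0.0488). The fixed factors were not called: ZEB1 measured 13.4 ± 0.424 and 22.6 ± 21.9 TPM, ZEB2 1.14 ± 0.651 and 1.99 ± 0.778 TPM, SNAI2 0.525 ± 0.672 and 3.60 ± 3.59 TPM, and TWIST1 1.73 ± 0.184 and 1.40 ± 0.424 TPM. SNAI2 was called with the replicate block (adjusted p = 0.0302 by limma). VIM measured 896 ± 312 TPM, CDH2 96.6 ± 63.6 TPM and COL4A1 127 ± 127 TPM at 96 h; CDH2 and COL4A1 were called with the block (adjusted p = 0.00119 and 0.0179 by limma). EPCAM, an epithelial adhesion molecule, measured 4.42 ± 0.148 and 1.92 ± 0.841 TPM, and MMP9 0.1 ± 0.113 and 0.285 ± 0.318 TPM. ESRP1, an epithelial splicing regulator, did not pass the filter, at 0.2 and 0.23 TPM at 0 h and 0.03 and 0.05 TPM at 96 h.

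SMAD-induced targets differed between the libraries of 96 h. Their median log2 change from the 0 h library of the same number was 1.60 in replicate 1 and -0.06 in replicate 2, and 1.49 and 0.57 with TMM scaling. Of the 21 targets, 1 rose at 96 h (2 adjusted over the list alone, 6 with the replicate block; camera adjusted p = 5.5e-10, adjusted p = 0.63 with an estimated correlation). SMAD3, which carries the TGF-beta signal to the nucleus, fell from 68.2 ± 13.7 to 14.8 ± 6.27 TPM. The vasodilator peptide gene ADM and the glycolysis regulator PFKFB3 fell with log2 fold changes of -3.14 and -1.68, and the fibrinogen gene FGB with -2.88. Its partner FGA fell from 17.8 ± 14.7 to 1.24 ± 1.54 TPM.

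In all, 91 genes were called higher and 213 lower at 96 h by limma, against 255 and 562 with the replicate block and 257 and 193 with TMM scaling, with which CDH1, KRT18, KRT19, LLGL2, FGA, AKR1C2 and SLPI missed the threshold (adjusted p = 0.0543, 0.259, 0.0953, 0.0733, 0.0863, 0.113 and 0.0506). Fewer genes were called without 0 h replicate 2, 96 h replicate 1 or 0 h replicate 1, and more without 96 h replicate 2. A fit of only 0 and 96 h called 0.

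**Figure D3:**
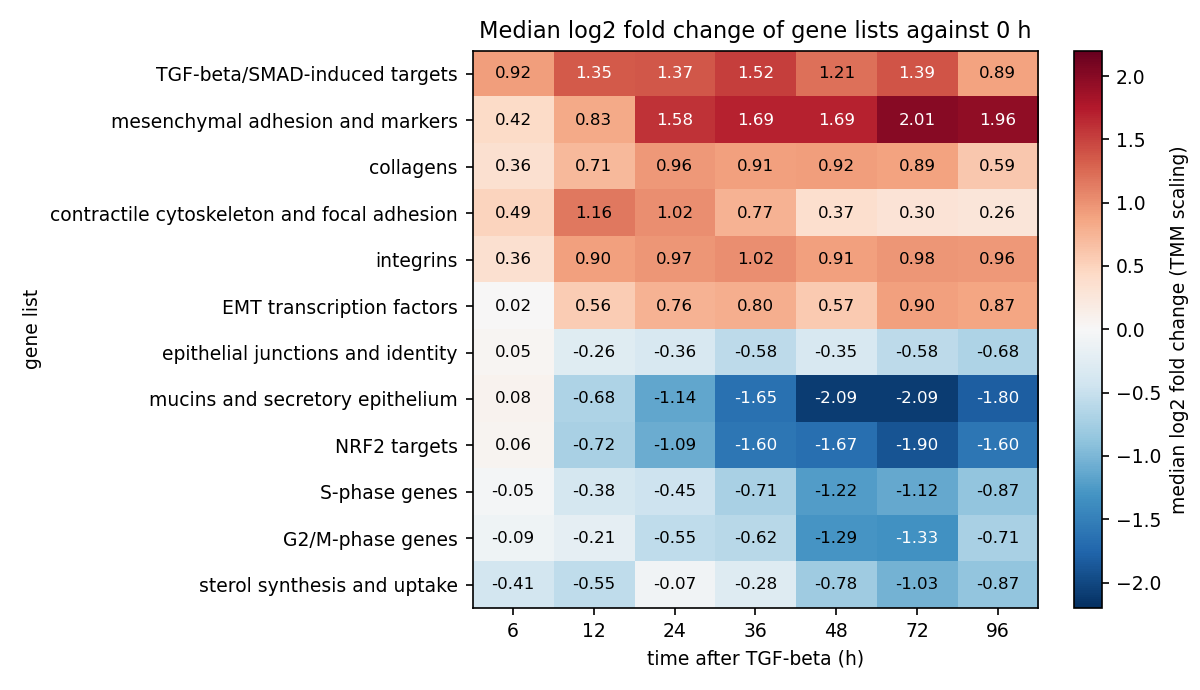
Median log2 fold change against 0 h (colour and printed value, TMM scaling) for 12 gene lists (rows) at 7 times (columns, hours). The SMAD-induced targets were highest at 36 h (1.52), the mesenchymal list at 72 h (2.01), and the NRF2 targets lowest at 72 h (-1.90).

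The fall of NRF2 targets and secretory genes was also seen at the times in between. Of the 27 NRF2 targets, 4 fell at 12 h, 17 at 36 h, 25 at 48 h and 20 at 72 h, with medians of -0.67, -1.75, -2.18 and -2.11 log2. With the replicate block 5, 23, 25 and 25 fell. The number of called mucin and secretory genes was 1 at 12 h, 4 at 36 h and 6 at 48 and 72 h, all lower. With the block these were 1, 7, 8 and 8. Of the S-phase genes, 23 of 30 were called lower at 48 h and 2 at 72 h. With the block these were 29 and 9. The median of the S-phase genes at 48 h was -1.68, and -1.22 with TMM scaling. At that time the median of the 13 mitochondrially encoded transcripts, a list for RNA quality, was -1.53 (-0.999 with TMM scaling), with 0 called and 10 called lower with the block, and the median of all genes was -0.46 (-0.05 with TMM scaling). Genes called higher and lower by limma numbered 43 and 22 at 12 h, 164 and 226 at 36 h, 135 and 1154 at 48 h, and 141 and 296 at 72 h. With the replicate block these were 326 and 116, 421 and 534, 288 and 2534, and 353 and 716, and with TMM scaling 145 and 49, 431 and 258, 415 and 428, and 364 and 278. Without 48 h replicate 1 the count at 48 h was 96, 41 higher and 55 lower. The F test over the whole course called 292 genes, 1040 with the block.

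From 12 h against 6 h onward, no gene was called by limma between a time and the one before it, so no gene is named for these steps. The genes with an unadjusted p below 0.05 numbered 1987 at 12 h against 6 h, 214 at 24 h against 12 h, 128 at 36 h against 24 h, 1070 at 48 h against 36 h, 362 at 72 h against 48 h and 44 at 96 h against 72 h. Without any change, a share of 0.05 of the 16967 genes would lie below this p. Of the 1987, 1966 were higher and 21 lower, against 699 and 642 with TMM scaling. Of the 1070, 30 were higher and 1040 lower, against 344 and 633 with TMM scaling. These steps involve 6 h and 48 h replicate 1, which had the lowest TMM factors (0.745 and 0.711). The counts as deposited cannot tell a shift in scale from a change in expression. With the replicate block 1 gene was called at 24 h against 12 h.

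The direct comparison of 96 h with 6 h asked which changes came after 6 h. IGFL2, COL22A1, IGFL3 and ITGA11 had the largest log2 fold changes against 0 h of the 33 genes that rose late, meaning no call at 6 h and a rise at 96 h against both 0 and 6 h. AGR2, ALDH3A1, CEACAM6, SLPI and ABCG2 led the 37 that fell late. Late means only after 6 h here: COL22A1 and AGR2 were already among the largest rises and falls at 24 h. The NRF2 targets were lower at 96 h than at 6 h (median difference -1.23, camera adjusted p = 8.21e-34, adjusted p = 0.0221 with an estimated correlation, a test of lists added after the data were seen), and FN1 and VCAN were higher by 3.56 and 2.83 log2 units (adjusted p = 0.0212 for both by limma). GDF15, SDPR and RP11-215G15.5 made up the 3 genes that fell early and stayed lower. The classes of transient rise, transient fall and early and kept rise held 0 genes, where TMM scaling put 12, 2 and 10 and the block 1, 1 and 3. In the main fit no gene was called higher at 6 h, so neither of the rise classes could hold a gene. Only 3 genes were called at 6 h, so the lack of a call there defines a late change only weakly. The late classes held 102 and 68 genes with TMM scaling and 138 and 156 with the block. In all, 56 genes were higher and 54 lower at 96 h than at 6 h, against 256 and 220 with the replicate block and 225 and 249 with TMM scaling. Far fewer were called in a fit of only 6 and 96 h, and leaving out single libraries moved the count both ways.

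The calls of 6 and 96 h shared 3 genes, all lower, where 0.0377 would be shared by independent lists. Simulated unchanged groups against the same 0 h libraries shared 0. They held no changed genes, so hardly any calls were possible, and this 0 cannot measure the effect of the shared 0 h libraries. Fold changes at 6 and 96 h correlated across genes, which are not independent replicates, at 0.446 with a covariance of 0.110; simulated unchanged groups gave 0.501 and 0.0780. Part of the overlap may come from the shared 0 h libraries, of which there are too few to divide.

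Libraries of the same time correlated at 0.940 (96 h) to 0.985 (6 h) across genes, with a median of 0.959. The median over different times was 0.964 for the same replicate number and 0.950 for different numbers, and the closest library was the other replicate of the same time for 3 of the 16 libraries. The immediate early genes EGR1 and FOS separated libraries of replicate 1 from each other: EGR1 was at 0.09 and 0.13 TPM in those of 6 and 48 h and at 8.99 TPM or more in the other 6. In replicate 2 it was at 0.21 TPM or less, and FOS was at 0.54 to 7.45 TPM. The median change of mitochondrially encoded transcripts from 0 h was -1.42 and -1.78 in replicate 1 at 6 and 48 h, against -0.45 to 0.64 at its other times, and -1.54 to -0.93 in replicate 2. The TMM factors of these libraries of 6 and 48 h were 0.745 and 0.711, against 1.06 or more in the others of replicate 1. The camera adjusted p of the mitochondrially encoded transcripts was 0.346 at 24 h and 0.752 at 96 h. That of 13 replication-dependent histones, a list for polyA selection, was 0.432, 0.00344 and 0.579 at 6, 24 and 96 h (medians -0.23, -0.55 and -0.26, adjusted p = 0.921, 0.76 and 0.933 with an estimated correlation). The 30 S-phase genes had a median of -0.60 at 24 h (camera adjusted p = 0.000429, adjusted p = 0.835 with an estimated correlation). The histone values at 24 h therefore cannot tell library preparation from the cell cycle.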

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

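The test of gene lists between 96 and 6 h was added after the data were seen, and the test of genes was planned. Of the genes named, 22 had a response at 96 h that differed from that at 6 h in the direct limma comparison (adjusted p from 0.00197 to 0.0469), and each is given here as the log2 fold change at 96 h minus that at 6 h. Some genes were named for the late classes, which need a call in this same comparison. The count of 22 is therefore partly set by the choice of genes. The 13 higher at 96 h were IGFL2 (5.43), IGFL3 (4.49), ITGA11 (4.03), COL22A1 (3.86), FN1 (3.56), GREM1 (2.87), CXCL1 (2.85), VCAN (2.83), NT5E (2.41), IGFBP7 (2.18), IFI44 (1.78), IFI44L (1.56) and SOX4 (1.49). The 9 lower at 96 h were AGR2 (-5.27), CEACAM6 (-4.23), SLPI (-4.22), ALDH3A1 (-3.97), AKR1B10 (-2.73), ABCG2 (-2.61), CLDN4 (-2.32), CA12 (-2.21) and CNN1 (-1.93). CLDN4 and CNN1, which rose at 24 h, are among the lower ones. The NRF2 targets differed as a list, with a median of -1.23, and were the 1 list of 19 called by camera that was also called with an estimated correlation (adjusted p = 0.0221).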

How the results depend on the processing

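Chosen after the data were seen were TMM scaling together with the replicate block, the rescaling without small RNAs, the rescaling over protein-coding genes, the removal of 6 h replicate 1 with 48 h replicate 1, and the combination with an estimated correlation. Of the 114 values of named genes, of which 88 were called, the replicate block ended 0 calls and added 10, while TMM scaling ended 11 and added 2, no filter ended 40, and a fit of only the times compared ended 48 and added 3. None of these settings turned a direction among the named genes. Besides these and the counts given for the block, the block changed 4 camera calls of lists: ribosome biogenesis and MYC targets at 6 h (adjusted p from 0.0249 to 0.0534), mitochondrially encoded transcripts at 6 h (adjusted p from 0.111 to 0.000735), ribosome biogenesis and MYC targets at 24 h (adjusted p from 0.104 to 0.043) and hypoxia and glycolysis at 96 h (adjusted p from 0.0354 to 0.0647). It changed no other call of a named gene or of a list against 0 h. It also changed the number of called members of lists, given with those lists. Every alternative set before the data were examined was run, but a filter of 5 TPM removed the genes of 12 values. Calls that ended numbered 14 with a pseudocount of 0.1, 8 with a pseudocount of 5, 7 with a filter of 5 TPM, 11 with quantile normalization, 2 with no trend, 1 with robust moderation, 1 with TMM scaling and the block, 11 with rescaling without small RNAs, 7 with rescaling over protein-coding genes and 30 with 6 h and 48 h replicate 1 left out. The largest dependence was on single libraries: 85 calls ended without 0 h replicate 2, 48 without 0 h replicate 1, 34 and 41 of those at 24 h without its replicates 1 and 2, and 32 and 4 of those at 96 h. When a library was left out, the lone library of its time was assumed to vary like the others. Fewer libraries lower the power by construction; for all other changes the cause was not tested. Depth is unknown, so its limits cannot be given.

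Counts that moved by over 1.5 times, and other values that moved, were these. A pseudocount of 0.1 gave 1 for genes changed, 6 h against 0 h, 1 for early and kept rise, 0 for early and kept fall, 1 for the overlap of 6 and 96 h and 0.938 for the replicate correlation. A pseudocount of 5 gave 30 for 6 h against 0 h, 68 for genes changed, 96 h against 6 h, 1 for transient fall, 21 for late rise, 16 for late fall, 10 for early and kept fall and 25 for the overlap of 6 and 96 h. Without a filter the values were 46 for 6 h against 0 h, 115 for genes changed, 12 h against 0 h, 15 for genes changed, 12 h against 6 h, 19 for genes changed, 24 h against 12 h, 7 for genes changed, 36 h against 24 h, 1 for genes changed, 48 h against 36 h, 3 for genes changed, 72 h against 48 h, 17 for genes changed, 96 h against 72 h, 46 for 96 h against 6 h, 14 for late rise, 11 for late fall, 1 for early and kept rise, 7 for early and kept fall, 40 for the overlap of 6 and 96 h and 0.978 for the replicate correlation. A filter of 5 TPM gave 1 for 6 h against 0 h, 37 for 12 h against 0 h, 134 for genes changed, 24 h against 0 h, 1 for early and kept fall, 1 for the overlap of 6 and 96 h and 0.937 for the replicate correlation. TMM scaling gave 49 for 6 h against 0 h, 194 for 12 h against 0 h, 478 for 24 h against 0 h, 689 for genes changed, 36 h against 0 h, 843 for genes changed, 48 h against 0 h, 1 for 72 h against 48 h, 474 for 96 h against 6 h, 557 for genes changed over the time course, 12 for transient rise, 2 for transient fall, 102 for late rise, 68 for late fall, 10 for early and kept rise, 7 for early and kept fall, 18 for the overlap of 6 and 96 h and 10 for gene lists at 6 h. Quantile normalization gave 15 for 6 h against 0 h, 206 for 12 h against 0 h, 473 for 24 h against 0 h, 720 for 36 h against 0 h, 810 for 48 h against 0 h, 759 for genes changed, 72 h against 0 h, 487 for genes changed, 96 h against 0 h, 381 for 96 h against 6 h, 533 for the whole course, 5 for transient rise, 93 for late rise, 4 for early and kept rise, 8 for the overlap of 6 and 96 h and 7 for gene lists at 6 h. With the replicate block the values were 12 for 6 h against 0 h, 442 for 12 h against 0 h, 643 for 24 h against 0 h, 955 for 36 h against 0 h, 2822 for 48 h against 0 h, 1069 for 72 h against 0 h, 817 for 96 h against 0 h, 1 for 24 h against 12 h, 476 for 96 h against 6 h, 1040 for the whole course, 1 for transient rise, 1 for transient fall, 138 for late rise, 156 for late fall, 3 for early and kept rise, 5 for early and kept fall and 9 for the overlap of 6 and 96 h. TMM scaling with the replicate block gave 359 for 6 h against 0 h, 865 for 12 h against 0 h, 1203 for 24 h against 0 h, 1601 for 36 h against 0 h, 2066 for 48 h against 0 h, 1690 for 72 h against 0 h, 1316 for 96 h against 0 h, 1 for 72 h against 48 h, 1504 for 96 h against 6 h, 1952 for the whole course, 60 for transient rise, 10 for transient fall, 200 for late rise, 192 for late fall, 61 for early and kept rise, 24 for early and kept fall and 142 for the overlap of 6 and 96 h. TPM rescaled without the 6 small RNAs gave 8 for 6 h against 0 h, 163 for 12 h against 0 h, 398 for 24 h against 0 h, 615 for 36 h against 0 h, 361 for 96 h against 6 h, 469 for the whole course, 1 for transient rise, 102 for late rise, 71 for late fall, 4 for early and kept rise and 7 for the overlap of 6 and 96 h. TPM rescaled over protein-coding genes gave 24 for 6 h against 0 h, 182 for 12 h against 0 h, 437 for 24 h against 0 h, 631 for 36 h against 0 h, 657 for 72 h against 0 h, 480 for 96 h against 0 h, 476 for 96 h against 6 h, 537 for the whole course, 5 for transient rise, 1 for transient fall, 106 for late rise, 80 for late fall, 7 for early and kept rise, 5 for early and kept fall and 13 for the overlap of 6 and 96 h. Leaving out 6 h replicate 1 and 48 h replicate 1 gave 0 for 6 h against 0 h, 4 for 12 h against 0 h, 117 for 24 h against 0 h, 256 for 36 h against 0 h, 29 for 48 h against 0 h, 11 for 96 h against 6 h, 51 for the whole course, 6 for late rise, 5 for late fall, 0 for early and kept fall, 0 for the overlap of 6 and 96 h and 10 for gene lists at 6 h. A fit of only the times compared gave 1 for 6 h against 0 h, 0 for 12 h against 0 h, 527 for 24 h against 0 h, 172 for 36 h against 0 h, 0 for 48 h against 0 h, 169 for 72 h against 0 h, 0 for 96 h against 0 h, 111 for 12 h against 6 h, 3 for 96 h against 6 h, 2 for late rise, 0 for late fall, 0 for early and kept fall and 0 for the overlap of 6 and 96 h. Camera with an estimated correlation gave 0 for gene lists at 6 h, 0 for gene lists at 24 h and 0 for gene lists at 96 h. Fry gave 0 for gene lists at 6 h, 2 for gene lists at 24 h and 3 for gene lists at 96 h. TMM scaling, the replicate block and an estimated correlation gave 0 for gene lists at 6 h, 4 for gene lists at 24 h and 4 for gene lists at 96 h.

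With 1 library left out, the lowest and highest values were 0 to 0 for genes changed, 6 h against 0 h, 0 to 18 for genes changed, 12 h against 0 h, 1 to 53 for genes changed, 24 h against 0 h, 3 to 160 for genes changed, 36 h against 0 h, 25 to 1165 for genes changed, 48 h against 0 h, 26 to 302 for genes changed, 72 h against 0 h, 6 to 435 for genes changed, 96 h against 0 h, 0 to 4 for genes changed, 12 h against 6 h, 0 to 4 for genes changed, 24 h against 12 h, 0 to 0 for genes changed, 36 h against 24 h, 0 to 0 for genes changed, 48 h against 36 h, 0 to 1 for genes changed, 72 h against 48 h, 0 to 1 for genes changed, 96 h against 72 h, 7 to 208 for genes changed, 96 h against 6 h, 55 to 614 for genes changed over the time course, 0 to 4 for transient rise, 0 to 0 for transient fall, 3 to 120 for late rise, 2 to 31 for late fall, 0 to 6 for early and kept rise, 0 to 3 for early and kept fall, 0 to 9 for the overlap of 6 and 96 h, 10 to 17 for gene lists at 6 h, 17 to 22 for gene lists at 24 h and 17 to 22 for gene lists at 96 h. The log2 fold changes that turned direction were -0.83 for ZEB1 at 96 h without 96 h replicate 1, -0.59 for CDKN1A at 96 h without 96 h replicate 1, -0.28 for CDKN1A at 96 h without 0 h replicate 2 and -0.050 for MMP9 at 96 h without 96 h replicate 1. With 1 library left out these genes ranged from -0.83 to 1.44 for ZEB1, 96 h against 0 h, -0.59 to 0.87 for CDKN1A, 96 h against 0 h and -0.050 to 0.46 for MMP9, 96 h against 0 h.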

Other observations

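The tests of a single library at 48 h, of a 0 h library in place of 96 h replicate 2, and of a swap and of scaling behind EGR1 and FOS were chosen after the result was seen. IFI44 and IFI44L, which are induced by interferon, rose at 96 h from 0.33 ± 0.311 to 3.33 ± 1.56 TPM and from 0.055 ± 0.0636 to 2.04 ± 0.615 TPM, and PSMB9, a subunit of the immunoproteasome, fell from 9.65 ± 1.17 to 2.13 ± 0.325 TPM. Of the 22 genes of this list, 2 rose and 1 fell (3 and 8 adjusted over the list alone, 2 and 3 with the replicate block; camera adjusted p = 0.539, adjusted p = 0.921 with an estimated correlation). Of the 23 extracellular proteases and inhibitors, 5 rose and 1 fell at 96 h (10 and 3 adjusted over the list alone, 8 and 3 with the replicate block; camera adjusted p = 6.88e-07, adjusted p = 0.631 with an estimated correlation), the member that fell being MMP24, a membrane-bound protease, from 26 ± 0.721 to 7.46 ± 2.88 TPM.

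At 24 h, WNT5B, a secreted Wnt ligand, rose from 0.87 ± 0.438 to 23.9 ± 4.68 TPM, and SLC2A3, a glucose transporter, rose from 21.5 ± 2.86 to 79.2 ± 19.1 TPM. RNF43, a ubiquitin ligase that lowers Wnt receptors, fell at 96 h from 7.67 ± 4.9 to 0.78 ± 0.877 TPM (adjusted p = 0.0797 with TMM scaling). TGFBR3, a TGF-beta co-receptor, fell at 24 h from 4.7 ± 0.856 to 0.75 ± 0.184 TPM. Of the 27 receptors and ligands of the TGF-beta family, 1 rose and 2 fell (4 and 5 adjusted over the list alone, 4 and 3 with the replicate block; camera adjusted p = 0.212, adjusted p = 0.921 with an estimated correlation). Of 20 inflammatory cytokines and NF-kB targets, 1 rose and 5 fell at 24 h (3 and 7 adjusted over the list alone, 3 and 6 with the replicate block; camera adjusted p = 0.183, adjusted p = 0.897 with an estimated correlation), among them CSF1, a macrophage growth factor, from 6.04 ± 0.12 to 1.2 ± 0.106 TPM, and TNFAIP2, from 106 ± 14.9 to 21 ± 2.11 TPM, both chosen for 24 h after their values were seen.

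At 48 h, 1154 of the 1289 genes called were lower, 2534 of 2822 with the replicate block, and 428 of 843 with TMM scaling, which centres most genes. Without 48 h replicate 1, the share of lower genes among those called was 57.3%. Far fewer genes were called without it, so this share cannot tell an effect of the library from a loss of power. The library stays a candidate source of the imbalance of calls. The median change of all genes was -0.54 in that library and -0.38 in 48 h replicate 2, but the other later libraries of replicate 2 lay between -0.48 and -0.25, so whether the lower median at 48 h is in replicate 1 alone stays open. With TPM rescaled without the 6 small RNAs the share was 67%, between the bounds set in advance of 60 and 75%. Whether the small RNA share is the cause of the imbalance of calls therefore stays open. The rescaling took the median change of all genes at 48 h from -0.54 to -0.27 in replicate 1. In replicate 2 it went from -0.38 to -0.18, so the small RNA share accounts for part of the lower median. A change in the cells at 48 h was not tested.

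The median change of SMAD-induced targets in 96 h replicate 2 was -0.06 with TPM as deposited, where that of all genes was -0.48, and 0.57 with TMM scaling. A 0 h library labelled 96 h is argued against by the NRF2 targets, whose median in that library was -1.83 as deposited and -1.19 with TMM scaling; a smaller share of 0 h material stays open. Scaling accounts for part of the pattern, and is argued against as the whole of it by the difference between the replicates, which was -0.92 with TMM scaling. A response that wanes by 96 h in this culture may account for the rest, which was not tested.

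EGR1 and FOS were high in 6 of the 8 libraries of replicate 1. A swap of replicates 1 and 2 at 6 and 48 h is argued against by EGR1 in replicate 2 at those times, at most 0.14 TPM, and scaling by the TMM factors, of which the highest was 2.15 times the lowest, while EGR1 was at 8.99 TPM or more in those 6 libraries and at 0.21 TPM or less in replicate 2. The other 2 libraries of replicate 1, of 6 and 48 h, had the largest falls of mitochondrially encoded transcripts in replicate 1 (medians -1.42 and -1.78) and its lowest TMM factors. RNA quality and handling before lysis could act on such genes and were not tested, and no biological explanation was tested.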
